A study of Caenorhabditis elegans with 58 samples.

How the data were processed

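Small RNAs were sequenced from C. elegans grown in bulk liquid culture and bleached for embryos, which were collected or held overnight without food to give starved L1. By the labels this description covers all 58 libraries, and how the staged embryos of the second part were picked is not given in the sources used here. Libraries were made with a commercial small-RNA kit with modifications, to which spike-in RNAs had been added. Per the submitters' processing notes, the tools were cutadapt 3.4, Bowtie2 2.4.4, SAMtools 1.13, HTSeq 0.13.5 and DESeq2, whose version is not given; the genome build is not given in the sources used here, so no coordinates are printed. In the annotation supplied with the reference, the 8 family genes lie on 1 chromosome and 7 of them stand next to each other among miRNA genes. The design text of the series describes an Argonaute experiment that none of the sample labels match, and it was not used.

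The table deposited by the authors holds estimated counts per miRNA arm, before any scaling. In it, 510 values in 129 of 296 table lines end in 0.5, for a cause that was not tested, and values were rounded to whole counts. Of the 296 lines, 276 are miRNA arms, 10 are spike-ins and 10 are the edited mir-35 sequences, 2 arms for each of 5 alleles. Values of mir-44 and mir-45, whose ratio was 0.949 to 1.07, are uncertain because their reads are shared. Total miRNA counts ranged from 3447390 to 20402800 in the allele part and from 170758 to 4059400 in the staged part. Replicates differed by more than counting error: the lowest chi-square per degree of freedom between a pair of replicates was 763 in the allele part and 102 in the staged part. Spike-in counts were 0.0899 to 0.792 of the miRNA counts in the allele part and 0.155 to 1.51 in the staged part. The make-up of the spike-ins was not constant. The spike-in miR166a was 40.5 to 79.4% of spike-in counts in the allele part and 7.69 to 15.7% in the staged part. Scaling by the summed spike-ins is therefore uncertain. There were no molecular identifiers, so floors cover counting error only, and amplified copies are not independent molecules.

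Groups, comparisons, tests, lists and alternatives were fixed before the data were examined, except where said otherwise. For the allele part the rule had been to sum all mir-35 allele sequences per library. This was changed after the table was seen, because the sequences of seed_rev and seed_rev_no_bulge hold the same reads (ratio 0.856 to 1.19 over 12 libraries) and every library holds some reads of other strains' alleles. Each strain's mir-35 was therefore taken from its own allele sequence, and the summed values are printed beside. The labels of the edited strains were checked by these sequences: the lowest own library was at least 2.69 times the highest other library of the same stage (setting the pair that shares reads apart), the least for mir-82_3' in L1 (81.9 against 30.5 CPM by plain library totals; other CPM use TMM factors). The labels of seed_rev and seed_rev_no_bulge were therefore not checked against each other. The ebax-1 genotype cannot be checked from miRNA counts.

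All arms were tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, in 1 fit of the 42 allele libraries and 1 of the 16 staged libraries, with no covariate, TMM factors, filterByExpr (minimum count 10, total 15) and Benjamini-Hochberg adjustment over all arms kept, with a threshold of 0.05. This kept 229 arms with a biological coefficient of variation of 0.453 in the allele part, and 198 arms with 1.04 in the staged part. Where every library of a group was at 0, the floor was 3 counts over the group. DESeq2 1.42.0 was an alternative. Lists were tested with fry and camera of limma 3.58.1 (preset correlation 0.01, then estimated) and adjusted over the lists. The 11 lists were the mir-35 family guides, the family passengers, the cluster siblings of mir-35, the mir-51, mir-58, mir-44, mir-64 and mir-2 families, the let-7 family with lin-4, tissue markers, and miRNAs from earlier work on EBAX-1. Of their members, mir-793 and mir-58b have no line in the table, and mir-247, mir-43 and mir-797 are in 2 lists each. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

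Named miRNAs were mir-35 and its family in every comparison, and up to 10 rises and 10 falls (5 each for an edited strain against wild type) with the largest change among those past the threshold, with a mean log2 CPM of at least 5 and groups that did not overlap, with list members as examples. Alternatives set in advance were RLE factors, library totals, TMM factors without the family, DESeq2, no filter, a minimum of 50 counts in every library of a group, replicate blocks, fits of the compared groups only, wild type of the same runs only, and each library left out in turn. Added after seeing the data were spike-in scaling, summed allele sequences, fits without the doubted libraries (TMM factor under 0.75 in the allele part: mir-82_3' L1 replicate 1, seed_rev_no_bulge L1 replicate 1 and wild-type embryo replicate 5; under 5e+05 counts in the staged part: wild-type 2 to 8 cell replicate 1, ebax-1 2 to 8 cell replicate 2 and ebax-1 starved L1 replicate 1), crossed numbers at pretzel, the paired permutation, the comparison of seed_rev_no_bulge with seed_rev and of starved L1 with comma, each list under each scaling, lists without members at 0 counts or without mir-45, the joined sequences of seed_rev and seed_rev_no_bulge, and splits that part as many same-run pairs as the real one.

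Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means, over arms with a mean log2 CPM of at least 5. In the allele part, numbered by runs of neighbouring sample identifiers, every pair was over 0.1 in 11 of 16 comparisons, wild-type embryos against L1 among them (0.158 to 0.525), which was taken as pairing. The staged part has 2 libraries per group, so both pairs give 1 value, too few to show pairing. It was 0.187 at the 2 to 8 cell stage, 0.274 at comma, -0.167 at pretzel and 0.050 in starved L1. The labels do not say whether libraries of a group came from separate cultures, so p-values measure a spread between libraries that may be technical.

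The fits were tested on 10 simulated data sets made from the real libraries. Wild-type L1 against embryos recovered 31.9% of changes of 2-fold, 85.3% of 4-fold and 98.3% of 8-fold, with 3.47% of calls false. For seed_rev against wild type in L1 these were 26.5, 91.4 and 98.3%, with 11.9% of calls false, above the nominal rate. For ebax-1 against wild type in starved L1 none of the changes of 2-fold or 4-fold and 10.3% of those of 8-fold were recovered. Fry found a simulated family shift of 1 log2 in 0 of 10 sets.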

Results

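Small-RNA libraries of the nematode Caenorhabditis elegans were counted per mature microRNA (miRNA) arm in 58 libraries that fall into 2 parts. The first part held 42 libraries of mixed embryos and of first-stage larvae (L1) from wild type and from 5 strains in which the mir-35 gene was edited. Wild type had 6 libraries per stage and each edited strain had 3. The labels name the alleles seed_rev, seed_mut, mut_3', mir-82_3' and seed_rev_no_bulge. They are read here as a reversed seed, a mutated seed, a mutated 3' part, a 3' part taken from mir-82, and a reversed seed without a bulge, whose place the labels do not give. The seed is the stretch near the 5' end through which a miRNA pairs with its targets. Guide reads of seed_rev and seed_rev_no_bulge spread about evenly over the sequences listed for both, so the counts show no difference between their guides. The second part held 16 libraries of wild type and of an ebax-1 null strain at the 2 to 8 cell, comma, pretzel and starved L1 stages, with 2 libraries per group. EBAX-1 is the substrate receptor of a ubiquitin ligase that has been linked to the degradation of miRNAs by their targets. The libraries of the first part held 3447390 to 20402800 miRNA counts. Those of the second part held 170758 to 4059400. Guides are named below by their gene and passenger strands by gene, arm and asterisk. Which arm counts as the passenger was taken from the asterisk in the deposited names, which need not mark the less active strand.

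The first comparison asked how the miRNAs of wild type differed between embryos and L1. The mir-35 family, which is essential for embryonic development, made up 35.5% ± 7.55 (SD, n = 6) of all miRNA counts in embryos and 1.44% ± 1.03 (n = 6) in L1. The difference was -34.0 points (2-sided exact permutation p = 0.00216, the smallest that 924 regroupings can give). These regroupings ignore the pairing of libraries by run, and a test that keeps the pairs could not reach so small a p. All 8 guides of the family fell, and each was lower in all 6 L1 libraries than in any embryo library. The largest falls were those of mir-38 (log2 -5.88, SE 0.53), mir-36 (-5.55), mir-41 (-5.55), mir-37 (-5.34) and mir-35 (-5.07, SE 0.49), and the smallest was that of mir-42 (-2.47, SE 0.26). Among the miRNAs that rose, mir-71, which promotes the survival of starved L1 larvae, went from a mean of 4769 CPM to 94571 CPM (log2 4.31, SE 0.64), where CPM is the count scaled to a common library total after correction by the TMM factor. The arm listed as mir-34_5p* rose by log2 4.22, mir-230 by 4.05, mir-84, a relative of let-7, by 3.14 (SE 0.29), and mir-238 by 2.85. Rises of at least 2.13 were found for mir-83, mir-63, mir-1821, mir-248 and mir-239a_3p*. Falls outside the family guides included those of mir-4813 (-5.17, SE 0.79), mir-39_5p* (-3.65) and mir-67_5p* (-3.08), among arms with a mean log2 CPM of at least 5 and groups that did not overlap. Of 229 miRNA arms tested by edgeR, 57 were higher and 71 lower in L1 at an adjusted p under 0.05, with 140 at an unadjusted p under 0.05. DESeq2 called 65 higher and 68 lower. The split depended on the scaling. Library totals moved the median of all arms by 0.35 and gave 76 higher and 51 lower. Spike-in counts, whose mix varied between libraries, moved it by 1.06 and gave 82 higher and 26 lower. Size factors of the RLE kind moved the median by 0.14.

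Groups of miRNAs fixed in advance were then tested between wild-type L1 and embryos. Counts adjusted over the list alone equalled those over all arms in each of the 11 lists of this comparison. The test fry asks whether the members of a list move, on balance, one way and does not compare the list with other miRNAs. For the 8 family guides the mean was -4.86 (fry adjusted p = 2.5e-17, and camera adjusted p = 0.0249 with an estimated correlation). For the 6 siblings of mir-35 in its cluster, all of which fell, it was -5.23 (adjusted p = 0.0249 with an estimated correlation). Of the 8 family passengers 7 fell and none rose, with a mean of -2.75 (fry adjusted p = 1.3e-05, and adjusted p = 0.537 with an estimated correlation). The other, mir-42_5p*, was at 0.33. In the let-7 family with lin-4, the miRNAs that time larval development, 5 of 8 members rose, 2 fell and 1 did not pass. The mean was 1.39 (fry adjusted p = 1.2e-09, and camera adjusted p = 0.324 with an estimated correlation). The risers were mir-794 (4.19), mir-237 (4.03), mir-84, lin-4 (2.57) and mir-795 (1.28). The members mir-48 (-1.64) and mir-241 (-2.13) fell. Of 6 miRNAs that earlier work had tied to EBAX-1, mir-243 rose (1.71) while mir-247 (-1.40), mir-788 (-1.10) and mir-43 (-0.88) fell. That list had a mean of -0.47 (fry adjusted p = 0.00168, and adjusted p = 0.940 with an estimated correlation), which turned to 0.57 under spike-in scaling, where mir-43 was at 0.19. In the mir-58 family, related to bantam, mir-80 rose (1.22) and mir-82 (-0.83, but 0.08 under spike-in scaling) and mir-2209a (-1.12) fell among 5 members (fry adjusted p = 0.497). In the mir-64 family mir-63 rose and mir-65 (-1.59) and mir-64 (-1.07) fell among 5 (fry adjusted p = 0.693). Only mir-51 (-1.83) fell among the 6 members of the mir-51 family, which is needed in embryos (fry adjusted p = 0.693). Only mir-247 fell among 4 in the mir-44 family (fry adjusted p = 0.716, but 0.0268 for a mean of 0.94 under spike-in scaling), and only mir-43 among 4 in the mir-2 family (fry adjusted p = 0.460). None of the 3 tissue markers, mir-1 of muscle and mir-124 and lsy-6 of neurons, passed, and their mean was 0.31 (fry adjusted p = 0.110). Scaled by library totals it was 0.66 (fry adjusted p = 0.00933), and under RLE factors 0.42 (0.0488). Family guides, passengers and the let-7 list kept their direction under all 5 scalings. Under spike-in scaling none of the falls outside the mir-35 family named for these lists passed.

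The next comparison asked which part of mir-35 its decline from embryo to L1 depended on. Wild-type mir-35 went from 137194 ± 57731 CPM (SD, n = 6) in embryos to 4090 ± 3509 in L1, so that 2.98% remained (95% interval 1.49 to 5.95, edgeR adjusted p = 4.0e-11, lower in 6 of 6 L1 libraries). Guide reads of seed_rev and of seed_rev_no_bulge are spread about evenly over the 2 sequences listed for these alleles, so values from a strain's own sequence understate its level, about equally in both stages. The mir-35 of seed_rev went from 110496 ± 19419 CPM (n = 3) to 47682 ± 8408, and 43.2% remained (18.7 to 99.5). In seed_mut the level was far lower throughout, 321 ± 129 CPM in embryos and 138 ± 93.9 in L1, and 43.1% remained (18.7 to 99.4). Neither difference passed (edgeR adjusted p = 0.0969 for a log2 change of -1.21 and 0.0916 for -1.22, with L1 below embryos in 3 of 3 replicate numbers in each). With replicate blocks both did, at -1.23 (edgeR adjusted p = 0.0446) and -1.34 (adjusted p = 0.0303). Values for seed_mut also passed without L1 replicate 1 (-1.69, edgeR adjusted p = 0.0327) or embryo replicate 3 (-1.49, adjusted p = 0.0426). Under spike-in scaling, which is uncertain because the mix of spike-ins varied between libraries, seed_rev was at 0.080. Both strains with an altered 3' part lost mir-35. In mut_3' it went from 20241 ± 4000 to 379 ± 79.3 CPM, with 1.87% remaining (0.682 to 5.15, edgeR adjusted p = 3.2e-08, lower in 3 of 3). In mir-82_3' it went from 7849 ± 1115 to 324 ± 233 CPM, with 4.13% remaining (1.59 to 10.8, edgeR adjusted p = 9.7e-07, lower in 3 of 3). As background, L1 libraries of other strains held up to 88.6 CPM of the mut_3' sequence and up to 30.5 CPM of the mir-82_3' sequence, both scaled by plain library totals without the TMM factor. In seed_rev_no_bulge it fell from 63109 ± 19364 to 10869 ± 6075 CPM, with 17.2% remaining (7.20 to 41.2, edgeR adjusted p = 0.00117, lower in 3 of 3). With the 2 sequences joined, seed_rev went from 223684 to 98041 CPM (43.8% remaining) and seed_rev_no_bulge from 128664 to 19162 CPM (14.9%), beside 148112 and 4051 CPM for wild type in that fit.

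**Figure D1:**
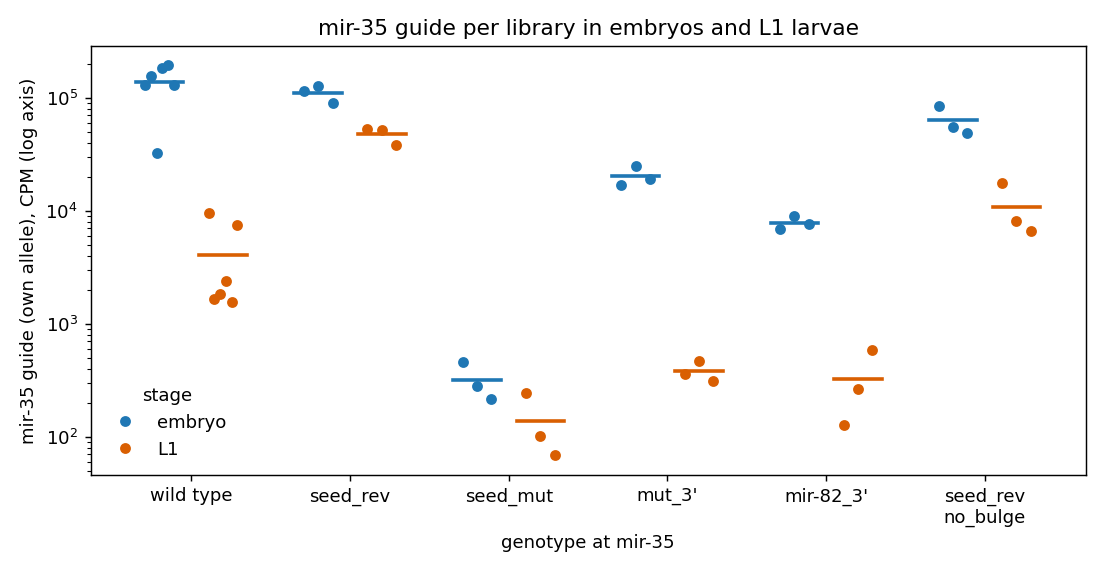
Level of the mir-35 guide in CPM on a log axis, counted in each strain's own mir-35 sequence, in embryo and L1 libraries of wild type (n = 6 per stage) and of the 5 edited strains (n = 3 per stage). Points are libraries and bars are group means. Wild-type means are 137194 and 4090, those of seed_rev are 110496 and 47682 in its own sequence, which holds only part of its guide reads (223684 and 98041 with the sequence that shares them), and both seed_mut means, 321 and 138, lie below the others of their stage.

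Differences between strains were tested directly, as the L1 to embryo change of an edited strain minus that of wild type. For seed_rev the difference was 3.86 (SE 0.75, 95% interval 2.33 to 5.38, edgeR adjusted p = 0.00210 over all arms), and for seed_mut it was 3.85 (SE 0.75, edgeR adjusted p = 0.00215). In each, all 3 edited replicate pairs kept more mir-35 (41.1 to 45.9% and 31.9 to 52.8%) than any of the 6 wild-type pairs (0.799 to 7.32%). For mut_3' the difference was -0.67 (interval -2.13 to 0.79, edgeR adjusted p = 0.996), with 3 pairs at 1.65 to 2.11%. For mir-82_3' it was 0.47 (interval -0.99 to 1.93, edgeR adjusted p = 0.973; -0.30 without L1 replicate 3), with 3 pairs at 1.84 to 7.64%. For seed_rev_no_bulge it was 2.53 (interval 1.04 to 4.02), with all 3 pairs at 13.5 to 20.9%. This last value did not pass over all arms (edgeR adjusted p = 0.320, but 0.0338 for 2.97 without wild-type L1 replicate 1), while adjusted over the 5 alleles alone p was 0.00233. Against seed_rev itself seed_rev_no_bulge differed by -1.33 (edgeR adjusted p = 0.675). These 2 strains share no run of neighbouring sample identifiers, so a difference between them cannot be told apart from one between runs. With the 2 sequences of these strains joined, the differences were 4.00 for seed_rev (adjusted p = 0.00106), 2.45 for seed_rev_no_bulge (0.414) and -1.56 between them (0.626). The 7 other family guides, not edited in these strains, had mean differences of 0.03 (SD 0.39) in seed_rev, 0.00 in seed_mut, -0.57 in mut_3', 0.30 in mir-82_3' and 0.21 in seed_rev_no_bulge, and none of them passed.

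**Figure D2:**
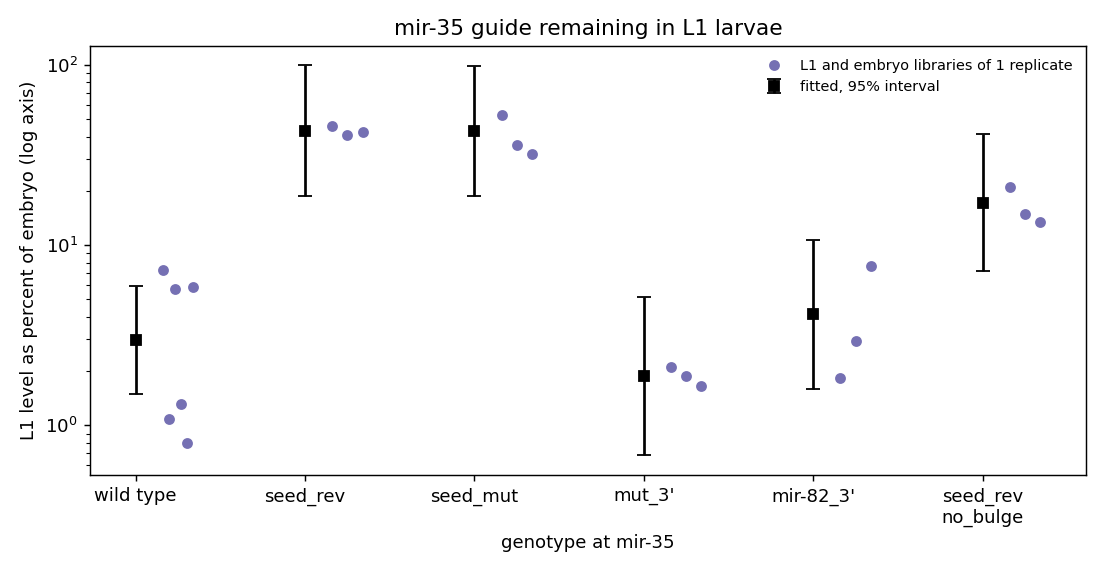
The mir-35 guide remaining in L1 as a percentage of the embryo level, on a log axis, for wild type and the 5 edited strains. Squares with bars are fitted values with 95% intervals and points are pairs of libraries with the same replicate number (6 for wild type, 3 for each edited strain); seed_rev at 43.2% and seed_mut at 43.1% lie above wild type at 2.98%, and seed_rev_no_bulge lies between at 17.2%.

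Exact permutations of genotype within stage (2-sided, 7056 regroupings) gave p = 0.00425 for seed_rev, 0.286 for seed_mut, 0.763 for mut_3', 0.844 for mir-82_3' and 0.0156 for seed_rev_no_bulge. These were 0.0213, 0.477, 0.844, 0.844 and 0.0390 when adjusted over the 5. Exact permutations of the paired L1 minus embryo values, chosen after the first set had been seen, gave 0.0119, 0.0119, 0.571, 0.679 and 0.0238 in the same order. Adjusted they were 0.0298, 0.0298, 0.679, 0.679 and 0.0397, and 0.0119 is the smallest that 84 splits can give. Both sets of permutations exchange libraries between runs and so ignore pairing by run. A paired test that kept the runs could not reach so small a p. The first test mixes level with decline, and seed_mut lay far below wild type at both stages. Libraries with neighbouring sample numbers form runs, and within the runs shared with wild type seed_rev kept 45.9, 41.1 and 42.6% where wild type kept 7.32, 1.08 and 5.68%. In the same runs seed_mut kept 52.8, 35.8 and 31.9%. In fits of only those 12 libraries the differences were 3.28 for seed_rev (edgeR adjusted p = 0.419) and 3.29 for seed_mut (edgeR adjusted p = 0.963), so neither passed over all arms. With all allele sequences summed, the rule set in advance, the differences were 3.94 for seed_rev (edgeR adjusted p = 2.1e-04), 4.75 for seed_mut (6.7e-06), -0.02 for mut_3', 1.81 for mir-82_3' (0.487) and 2.32 for seed_rev_no_bulge (0.251). Such sums also count reads of other strains' alleles. By plain library totals, seed_mut held 210 to 470 CPM of its own sequence in embryos and 81.3 to 219 in L1. The wild-type sequence alone had a median of 217 CPM in embryos and 152 in L1 of edited strains. Summed values of seed_mut, and of mut_3' and mir-82_3' in L1, therefore partly measure that background.

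Levels of mir-35 in each edited strain were also compared with wild type within a stage. In embryos, seed_rev was at log2 -0.31 (edgeR adjusted p = 0.984) and seed_rev_no_bulge at -1.12 (adjusted p = 0.993). Lower values were found for mut_3' at -2.76 (edgeR adjusted p = 0.00396), mir-82_3' at -4.13 (adjusted p = 3.0e-05) and seed_mut at -8.74 (adjusted p = 8.4e-11), each in 3 of 3 libraries. In L1, seed_rev was higher by 3.54 (SE 0.50, edgeR adjusted p = 2.0e-06, in 3 of 3 libraries), and seed_rev_no_bulge was at 1.41 (adjusted p = 0.162). These 4 values for seed_rev and seed_rev_no_bulge come from the own sequence and are too low. With the 2 sequences joined, seed_rev was at 0.59 in embryos (edgeR adjusted p = 0.971) and 4.60 in L1 (adjusted p = 5.6e-09). In the same fit seed_rev_no_bulge was at -0.20 in embryos (adjusted p = 0.994) and 2.24 in L1 (adjusted p = 0.00993), so its L1 level passed. In the fit of own sequences, the L1 levels of mut_3' (-3.43), mir-82_3' (-3.66) and seed_mut (-4.89) were lower, each past the edgeR threshold. The passenger mir-35_5p* was higher in embryos of seed_rev (5.13, edgeR adjusted p = 1.4e-08), seed_rev_no_bulge (4.44, adjusted p = 3.1e-07) and mut_3' (3.90, adjusted p = 4.4e-06), in 3 of 3 libraries each. Edited guides and passengers are different sequences from the wild-type ones, and sequence-dependent capture in library preparation was not measured. These levels hold that offset, and the L1 to embryo changes within a strain do not. Few other miRNAs differed between edited strains and wild type. In embryos, edgeR called 1 other arm for seed_rev (12 at unadjusted p under 0.05, DESeq2 1), which was mir-77_5p* (3.69), chosen here after its values were seen. That count was 0 without seed_rev embryo replicate 3 and 2 without wild-type embryo replicate 3. It called 0 for seed_mut (3 unadjusted, DESeq2 0), mut_3' (4, 0), mir-82_3' (2, 0) and seed_rev_no_bulge (1, 0). In L1, edgeR called 0 for seed_rev (2 unadjusted, DESeq2 0), seed_mut (7, 0), mut_3' (1, 0) and seed_rev_no_bulge (25, 1), and 6 for mir-82_3' (23, 9). For seed_mut the count was 1 without wild-type embryo replicate 2 in embryos and 1 without wild-type L1 replicate 3 in L1. Those 6 were mir-1819, mir-39_5p*, mir-41_5p*, mir-37_5p*, mir-796 and mir-1832a, named after their values were seen and all higher by 1.54 to 2.50. Their number fell to 0 without mir-82_3' L1 replicate 1, whose TMM factor was 0.648, to 0 without wild-type L1 replicate 2 or 5, to 1 without wild-type replicate 3 or 4 and to 3 without replicate 1. It rose to 13 without wild-type replicate 6, to 21 without mir-82_3' replicate 2 and to 11 without its replicate 3, and was 0 with replicate blocks. No list passed fry in any comparison of an edited strain with wild type.

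Wild-type embryos of known stage were compared step by step. From the 2 to 8 cell stage to comma, mir-42 rose by 4.85 (SE 0.93, edgeR adjusted p = 7.5e-04), mir-57, a relative of mir-10 that acts in posterior cell fate, by 3.91 (SE 0.80) and mir-228 by 3.73 (SE 0.79), each higher in 2 of 2 libraries. Further rises were those of mir-90_5p* (5.33), mir-54_5p* (4.84), mir-87 (4.15), mir-49 (3.95) and mir-52 (3.32). The rise of mir-44 (3.43) and that of mir-45 are uncertain because these miRNAs share reads. Falls were those of mir-77_5p* (-7.35), mir-77 (-5.64), mir-241 (-4.47), mir-71_3p* (-3.61), mir-71 (-2.84, SE 0.67, edgeR adjusted p = 0.00219, lower in 2 of 2), let-7 (-2.84, SE 0.95), mir-253 (-2.82) and mir-70 (-2.31). In the mir-51 family 4 of 6 members rose, among them mir-56 (3.02) and mir-55 (2.76), with a mean of 2.31 (fry adjusted p = 0.0332, and adjusted p = 0.918 with an estimated correlation). In the let-7 list 3 of 7 fell, or 5 when adjusted over the list alone (mean -4.02, fry adjusted p = 0.0498, and adjusted p = 0.438 with an estimated correlation). Among them lin-4, at 0 counts in both comma libraries, was at or below a log2 bound of -7.21, from a floor of 3 counts over the group. The mir-44 family had 2 of 3 up (fry adjusted p = 0.0332, and adjusted p = 0.918 with an estimated correlation). These were mir-44 and mir-45, which share reads and are not separate measurements, and with mir-45 left out 1 of 2 was up (fry adjusted p = 0.124). The EBAX-1 list had 1 of 4 down, mir-253 (fry adjusted p = 0.0332, and adjusted p = 0.438 with an estimated correlation). In that list mir-43 had 0 counts in all 4 libraries. With it left out fry gave adjusted p of 0.0605 for the EBAX-1 list and, through the adjustment over lists, 0.0605 for the let-7 list. Each of these fry calls was lost under at least 1 other scaling, with adjusted p of 0.133 for the mir-51 list and 0.0968 for the mir-44 list under RLE factors, and 0.0999 for the let-7 list and 0.263 for the EBAX-1 list under spike-in scaling. Among the tissue markers mir-1 of muscle rose by 2.35, with 2 past when adjusted over the list alone (fry adjusted p = 0.0605). The 8 mir-35 family guides had a mean of 0.94 (fry adjusted p = 0.0742), which turned to -0.86 under RLE factors and -0.36 with TMM factors computed without the family, and was 1.98 under spike-in scaling (fry adjusted p = 0.0313). Of 198 arms edgeR called 33 higher and 10 lower (70 at unadjusted p under 0.05), and DESeq2 called 35 and 35. With TMM factors the median of all arms was 1.03. Other scalings gave splits of 20 and 14 (RLE), 23 and 15 (totals), 21 and 15 (TMM without the family) and 44 and 3 (spike-in). Under spike-in scaling only mir-77_5p* passed among the 8 falls named. A fit of these 4 libraries alone called 0 arms. Values for let-7, mir-70 and mir-71_3p* did not pass without 2 to 8 cell replicate 1 (-2.00, -1.31 and -1.37) or comma replicate 1 (-2.66, -2.02 and -3.12). Nor did mir-241 and mir-71_3p* without comma replicate 2 (-4.11 and -4.32), or mir-87, mir-90_5p* and mir-253 without 2 to 8 cell replicate 2 (3.18, 4.33 and -2.45).

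In the later steps the family was lower at each stage than at the one before. From comma to pretzel the 8 guides had a mean of -1.38, with 7 of 8 negative (fry adjusted p = 0.00739, and camera adjusted p = 0.158 with an estimated correlation), led by mir-37 (-2.12, SE 0.63) and mir-35 (-2.10, SE 0.60). No arm passed in edgeR (0, with 27 at unadjusted p under 0.05, and DESeq2 called 19), and 3 guides passed when adjusted over the list alone. From pretzel to starved L1 the mean was -1.48, with 8 of 8 negative (fry adjusted p = 0.00842, and adjusted p = 0.518 with an estimated correlation), mir-35 was at -1.95 (SE 0.59), and 2 guides passed when adjusted over the list alone. In that step edgeR called 1 arm, mir-71, higher by 3.29 (SE 0.69, adjusted p = 0.00381, in 2 of 2 libraries), with 28 at unadjusted p under 0.05 and 16 called by DESeq2. The sign of the family mean held under all 5 scalings in both steps, but the fry call of the first step was lost under each of the other 4 (largest adjusted p 0.338). It was lost also without any 1 of the 4 libraries, at -1.08 without comma replicate 1, -1.37 without comma replicate 2, -1.46 without pretzel replicate 1 and -1.12 without pretzel replicate 2. The fry call of the second step was lost under RLE factors, library totals and TMM factors without the family (adjusted p = 0.182, 0.103 and 0.193). For mir-71 the rise did not pass under spike-in scaling (2.41, adjusted p = 0.0702) or without pretzel replicate 1 (1.95, adjusted p = 0.0939). The number of arms called was 12, 15, 23 and 5 without pretzel replicate 1, pretzel replicate 2, starved L1 replicate 1 and starved L1 replicate 2.

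The last comparison asked how miRNAs differed without EBAX-1. In starved L1 the family guides made up 9.03% ± 0.616 (SD, n = 2) of miRNA counts in the ebax-1 strain and 4.04% ± 2.08 (n = 2) in wild type, and at pretzel 24.6% ± 7.71 and 11.2% ± 1.09. At comma they made up 40.4% ± 8.42 and 37.0% ± 9.88, and at the 2 to 8 cell stage 39.0% ± 17.1 and 40.1% ± 10.5. The guide of mir-35 was at 68093 ± 11069 CPM in starved L1 of the ebax-1 strain and 18552 ± 9028 in wild type, and the log2 difference was 1.88 (SE 0.59, edgeR adjusted p = 0.185, higher in 2 of 2 libraries). At pretzel the difference was 1.16 (SE 0.58). Over the 8 guides the mean difference in starved L1 was 1.07, with 8 of 8 positive (0.53 to 1.88). The fry adjusted p was 0.0339, with camera adjusted p = 0.388 with an estimated correlation, and 1 guide passed when adjusted over the list alone. It was 0.0508 once members of other lists that had 0 counts in all 4 libraries were left out. At pretzel the mean was 0.70, again with 8 of 8 positive (fry adjusted p = 0.182), at comma 0.27 (adjusted p = 0.716) and at the 2 to 8 cell stage 0.43 (adjusted p = 0.563). At that earliest stage the mean turned to -0.77 under RLE factors, and the median of all arms was 0.87 under TMM. The starved L1 call was fragile: fry gave 0.288 under RLE factors, 0.339 under library totals, 0.300 with TMM factors without the family and 0.0938 under spike-in scaling. It was also lost without each library: 2.30 without wild-type replicate 1, 0.73 without wild-type replicate 2, 1.22 without ebax-1 replicate 1 and 0.64 without ebax-1 replicate 2 (fry adjusted p = 0.141 to 0.655). The difference in starved L1 exceeded that at pretzel by 0.37 (fry adjusted p = 0.718) and that at comma by 0.80 (fry adjusted p = 0.259), so no change of the difference between stages passed. The 6 cluster siblings had a mean of 1.03 in starved L1 (fry adjusted p = 0.0339, or 0.0508 without those members, and camera adjusted p = 0.388 with an estimated correlation). Of the 4 miRNAs tied earlier to EBAX-1 that were tested, mir-43 and mir-788 had 0 counts in all 4 libraries. The other 2 were mir-253 at 2.60 (SE 0.81) and mir-243 at 0.55 (SE 1.26), with a mean of 1.58 (fry adjusted p = 0.1002), and neither passed over all arms. With the 2 members at 0 kept, as set in advance, the list had a mean of 0.79 and passed fry (adjusted p = 0.0339). Its camera adjusted p was 0.388 with an estimated correlation. No single arm passed in edgeR at any stage. The counts at unadjusted p under 0.05 were 23, 6, 4 and 22 from the 2 to 8 cell stage to starved L1, and DESeq2 called 7, 0, 0 and 13. Left-out libraries moved some of these counts from 0: to 19 at the 2 to 8 cell stage without ebax-1 replicate 2 and 8 without wild-type replicate 1, to 3 at comma without wild-type replicate 1, and in starved L1 to 7 without wild-type replicate 1 and 1 without any 1 of the other 3. Without 2 to 8 cell wild-type replicate 1 the family mean there was -0.62, and at comma it was -0.20 without wild-type replicate 2 and -0.27 without ebax-1 replicate 2.

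**Figure D3:**
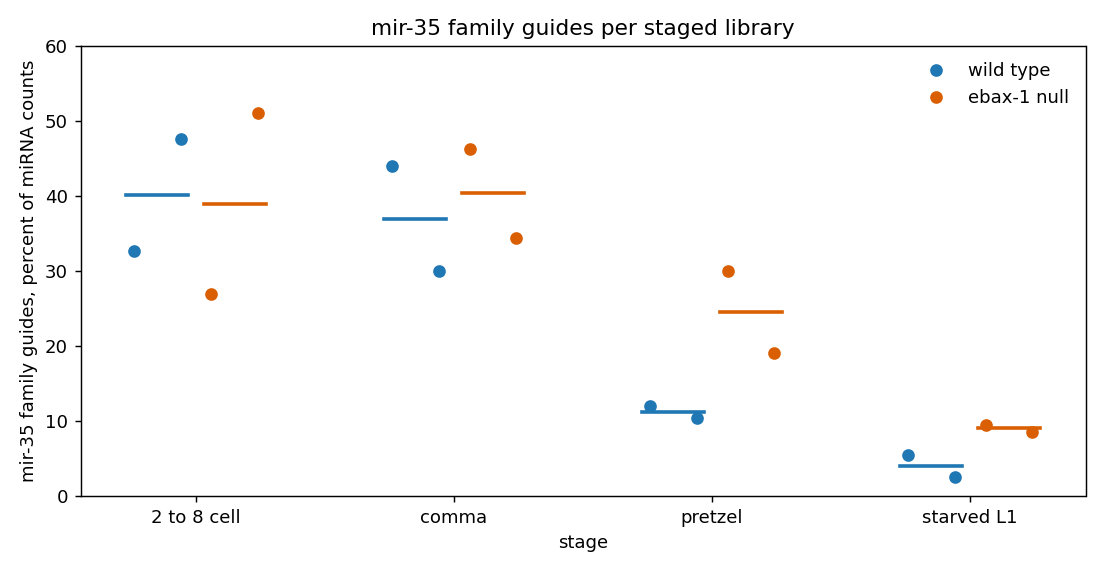
Share of the mir-35 family guides in all miRNA counts, in percent from 0 to 60, per staged library of wild type and the ebax-1 strain (2 per stage), with lines through the group means. In starved L1 the means are 9.03% in the ebax-1 strain and 4.04% in wild type. In fold terms the family difference kept its sign under all 5 scalings at pretzel, comma and starved L1, but turned at the 2 to 8 cell stage (0.43 under TMM, -0.77 under RLE factors).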

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

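The tests of explanations in this part were chosen after the results they bear on had been seen. The L1 to embryo change of mir-35 differed from wild type in 2 edited strains by a direct test of the difference, by 3.86 in seed_rev and by 3.85 in seed_mut on the log2 scale. Animals that were younger in the edited L1 libraries would have kept the other family guides too, but the larger mean difference of the 7 others was 0.027 (SD 0.39), which argues against age as the whole cause. Reads from other libraries are argued against by the lowest L1 library of these strains, which held 71.6 times as much of its own allele as the highest library of a strain without that sequence. Scaling is argued against by the smallest difference over 5 scalings, 3.42. A decline that may depend on the seed is a hypothesis that remains, found and tested on the same data. Bearing on that hypothesis, seed_rev_no_bulge, by its label also a reversed seed, kept 17.2% where seed_rev kept 43.2%. Its difference from wild type was 2.53 (interval 1.04 to 4.02). This did not pass over all arms (edgeR adjusted p = 0.320) but did over the 5 alleles alone (edgeR adjusted p = 0.00233). It passed also in the exact permutations adjusted over the 5, within stage (p = 0.0390) and paired (p = 0.0397). Both use the same libraries as the fit and ignore the runs, and the within-stage one mixes level with decline, so they are not separate evidence. Each pair of seed_rev_no_bulge kept more mir-35 (13.5 to 20.9%) than any wild-type pair (0.799 to 7.32%). From seed_rev it differed by -1.33 (edgeR adjusted p = 0.675). Whether these 2 strains differ is therefore open. Their guide reads spread about evenly over the 2 listed sequences, so the counts give no sign that a difference would lie in the seed. The hypothesis was not tested further. Still open are also the adjusted calls, which were lost in fits of the 12 libraries of the shared runs (3.28 and 3.29). So is the low level of seed_mut, at which an edited sequence could also differ in how it is made. The passenger mir-35_5p* of seed_rev was higher than in wild-type embryos (5.13), and whether its edit changes how mir-35 is made was not tested.

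A signal appeared in counts that the main fits did not use and only the summed alternative did. The wild-type mir-35 sequence was listed in all 30 edited libraries, at a median of 179 CPM by plain library totals (38.6 to 683), above the 0.870 CPM that a count of 0 allows. For comparison, wild-type embryos held at least 32265 CPM on the same scale. Dixon's test was run on 7 measures in each of the 2 groups of 6 libraries, wild-type embryos and wild-type L1, 14 sets of values in all, and not on the smaller groups. In 1 set a library stood apart: the summed level of the 7 family guides other than mir-35 was 194904 CPM with TMM factors in wild-type embryo replicate 3, against 245254 in the nearest library. Chance flags about 1 set in 20, and the cause was not tested.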

How the results depend on the processing

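Spike-in scaling, summed allele sequences, fits without the doubted libraries (low TMM factor or low depth) and crossed numbers were chosen after seeing the data. Over 39 results and 730 alternatives from 75 settings, 609 were unchanged, 31 lost a call, 6 gained one, 84 moved and 0 turned the sign of a called value. Unchanged means direction and side of the threshold for a value with an adjusted p. For a count of arms it means a number close in size. A value without an adjusted p had to keep its sign and shift by less than its standard error. Moved covers larger shifts of counts and of such values, and turned signs of values not called. That tally leaves out lists other than the mir-35 family and their members, which were run under the 5 scalings only. Of 16 called lists 1 turned, the EBAX-1 list between wild-type L1 and embryos (0.57 with spike-ins). Of 46 called members 2 turned, mir-43 (0.19) and mir-82 (0.08), both in that comparison with spike-ins. For 266 single miRNAs, 4627 of 5165 alternatives were unchanged by the same rules. The fall of mir-35 in wild type, mut_3' and mir-82_3' and the differences for seed_rev and seed_mut passed under every scaling and every left-out library. Depth sets the counting floor, and totals began at 170758 counts in the staged part against 3447390 in the allele part. Except where a setting tests fewer samples or arms, the cause of a change was not tested.

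The replicate block by run changed the mir-35 value within seed_rev to -1.23 (adjusted p = 0.0446) and within seed_mut to -1.34 (adjusted p = 0.0303) and the mir-82_3' L1 count to 0, and it changed no other call in the allele part. In the staged part, where 2 libraries per group cannot show whether numbers pair them, the replicate block gave counts of 39, 0 and 1 for the wild-type steps. It ended the calls of mir-87 (3.99), let-7 (-2.78) and mir-70 (-2.25) at comma and changed no other call of a miRNA named or of the family. With the numbers of the ebax-1 pretzel libraries exchanged, since same-numbered libraries deviated apart there (-0.167), the replicate block called 0 arms.

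For ebax-1 against wild type, the 2 to 8 cell family mean was -0.77 with DESeq2 and with RLE factors, -0.037 with TMM factors without the family, -0.22 without a filter, -0.31 with a minimum of 50 counts and -0.20 in a fit of the groups alone. At comma it was -0.071 without a filter. In starved L1 it was 1.08 with RLE factors (fry adjusted p = 0.288), 0.74 with totals (0.339), 0.97 with TMM without the family (0.300), 1.01 without a filter (0.241), 0.98 with a minimum of 50 (0.242), 1.44 with spike-ins (0.0938), 1.25 without the doubted libraries (0.143) and 0.96 in the groups alone (0.190). The starved L1 minus pretzel difference was -0.10 with totals. Counts of 0 became 7 (2 to 8 cell) and 13 (starved L1) with DESeq2, 1 and 2 without a filter, 1 (starved L1) with totals and 3 (starved L1) in the groups alone. Without the doubted libraries they became 56, 2, 1 and 15 from the first stage to the last. The first of these compares 1 library with 1 and the last 1 ebax-1 library with 2, with a lone library assumed to vary like the other groups.

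For the wild-type steps, the comma family mean was -0.86 with DESeq2 and RLE factors, -0.36 with TMM without the family, -0.38 with a minimum of 50 and 1.98 with spike-ins (fry adjusted p = 0.0313). At pretzel it was -1.35 with RLE factors (0.238), -1.15 with totals (0.0507), -1.70 with TMM without the family (0.0642), -1.25 without a filter (0.132), -1.59 with a minimum of 50 (0.0673), -0.46 with spike-ins (0.338) and -1.44 in the groups alone (0.113). In starved L1 it was -1.47 with RLE factors (0.182), -1.28 with totals (0.103), -1.39 with TMM without the family (0.193), -1.46 with a minimum of 50 (0.0980), -1.42 in the groups alone (0.136) and -1.49 without the doubted libraries (0.0514). Counts of 33 and 10 at comma became 70 with DESeq2 and 0 in the groups alone. The pretzel count of 0 became 19 with DESeq2, 4 with totals, 2 with TMM without the family, 5 without a filter, 2 with a minimum of 50, 1 with spike-ins, 5 in the groups alone and 20 without the doubted libraries. The starved L1 count of 1 became 16 with DESeq2, 7 with totals, 25 without a filter, 2 with a minimum of 50, 3 with spike-ins and 17 without the doubted libraries.

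In the allele part, the mir-82_3' L1 count of 6 became 0 with totals, with TMM without the family, without a filter, with spike-ins, with summed alleles, with wild type of the same runs and without the doubted libraries. The seed_rev embryo count of 1 became 0 with a minimum of 50 and with wild type of the same runs, and the seed_rev_no_bulge L1 count of 0 became 1 with DESeq2. With wild type of the same runs, which tests fewer samples, the mir-35 differences were 3.28 for seed_rev and 3.29 for seed_mut, and neither passed. Wild-type replicates 4 to 6 alone called 76 arms between L1 and embryos against 128 with all 6. With the sequences of seed_rev and seed_rev_no_bulge joined, chosen after seeing the data and outside the tally, the L1 level of seed_rev_no_bulge against wild type went from 1.41 to 2.24 and passed, and no other mir-35 call of these strains changed. With spike-ins, mir-35 within seed_rev was at 0.080 and the difference for mut_3' at 0.17.

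Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave ranges of 0 to 19 (2 to 8 cell), 0 to 3 (comma) and 1 to 7 (starved L1) for ebax-1 counts, and family means of -0.62 to 0.37, -0.27 to 0.10 and 0.64 to 2.30. Wild-type steps gave a pretzel family mean of -1.46 to -1.08 and counts of 1 to 2 at pretzel and 5 to 23 in starved L1. The mir-35 value within seed_mut was -1.69 to -0.93, the difference for mir-82_3' was -0.30 to 0.92 and that for seed_rev_no_bulge 1.89 to 3.04. Counts of other arms were 0 to 21 for mir-82_3' in L1, 0 to 2 for seed_rev in embryos, and 0 to 1 for seed_mut in embryos and in L1.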

Other observations

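The tests of explanations in this part were chosen after the results they bear on had been seen. In each edited strain many other arms differed between L1 and embryos. Of these edgeR called 103 arms besides mir-35 for seed_rev (44 higher and 59 lower), 101 for seed_mut (44 and 57), 99 for mut_3' (47 and 52), 88 for mir-82_3' (49 and 39) and 90 for seed_rev_no_bulge (41 and 49). In the ebax-1 strain at pretzel, all 6 members of the mir-51 family were lower than in wild type, with a mean of -0.96 that kept its sign under all 5 scalings, though it did not pass fry (adjusted p = 0.182). At the same stage mir-253 was at 1.80 and in starved L1 at 2.60, and neither passed in edgeR.

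In starved L1 the 8 family guides were higher in the ebax-1 strain by a mean of 1.07. A slower loss of the family without EBAX-1 is a hypothesis that these data leave open, and so are 3 technical ones, which cannot be told apart from it. Younger ebax-1 animals may account for part. A regression of the ebax-1 difference on the L1 to embryo change of bulk wild type, over 80 arms outside the family, predicted a family shift of 0.32 (SE 0.31). Without the ebax-1 library of low depth the mean was 1.22 (SE 0.97), and the smallest mean over 5 scalings was 0.74, with fry calls lost in both. With 2 libraries per group the counts are too few to decide.

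From embryo to L1 of wild type the family guides fell further than their own passengers, by a mean of -2.11 over 8 pairs. Passengers near the counting floor are argued against by the 5 pairs with at least 50 passenger counts, whose mean was -2.18. A shift of guides against passengers in all miRNAs is argued against by the other 83 pairs, whose median was 0.76 (SD 1.495), with 3 at or below the family mean. Arms were called guide or passenger by the asterisk in the deposited names. One of those 3 pairs was mir-34 (-2.44). A loss that acts on the guide beyond a lower output of the hairpin is consistent with these values as a hypothesis, and it was not tested itself.

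Other splits of the same libraries were counted for each number of arms called. Between wild-type L1 and embryos 1 of 100 splits drawn from 462, the real one, gave as many as 128, and the highest other was 103, so chance is excluded at the level of 0.05. Runs pair these libraries, and of the 32 splits that part all 6 pairs again only the real one gave as many (highest other 83). The other splits mix embryos with L1. For seed_rev embryos 7 of 84 splits gave at least the real 1 (highest other 11), and for mir-82_3' L1 7 of 84 gave at least the real 6 (highest other 56), so chance cannot be excluded for either. The splits with 11 and 56 parted 0 and 1 of the 3 same-run pairs, while among the 8 splits that part all 3 the highest others were 1 and 2, too few splits for a share under 0.05. These 2 splits were picked as the highest of 84 each. For mir-82_3' L1 against wild type the numbers did not show pairing (correlations -0.406 to 0.532). Whether a structure of the libraries other than genotype lies behind them was not tested. Where the real count was 0, all 84 splits gave as many by construction, which decides nothing: the highest others were 1 for seed_rev in L1, 12 and 4 for seed_mut in embryos and L1, 5 and 19 for mut_3', 4 for mir-82_3' embryos, and 18 and 29 for seed_rev_no_bulge.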
